A study of Drosophila melanogaster with 2 samples.

How the data were processed

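Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on mixed-sex Drosophila melanogaster embryos aged 0 to 14 h. The line carries a GFP-tagged copy of CG8359, the gene now named hng2 (hinge2), a member of the MADF and BESS domain family of DNA-associated proteins. The labels differ on the antibody. Its entry names CG8359, while the sample description gives an antibody against GFP, and the description is followed here; which of them was used could not be checked from the peak lists. Per the labels, chromatin fragments of 200 to 800 bp were used. The 2 samples are biological replicates, numbered 2 and 3, and form 1 group. No control group is among the samples, and the control libraries behind the peak calls were not analysed here.

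The authors deposited 8 peak lists, 4 on genome build dm6 and 4 on dm3. On each build they called peaks in replicate 2, in replicate 3 and in both replicates pooled, each against a control alignment, with a relaxed threshold. From these lists the authors made an optimal list with the irreproducible discovery rate (IDR). The first value column of the deposited lists is the caller's signal for each peak against its control. It is not scaled to be compared between lists, so it was used only for ranks within a list and for description. The second is the caller's -log10 q-value per peak, as deposited by the authors. The third is the summit offset in bp from the peak start, as the authors deposited it, from which each summit position was computed. The peak caller, the aligner, their versions and the IDR threshold are not given in the sources used here. The lists hold no read counts, so the depth of each library is unknown. Intervals cover counting error over peaks, genes or windows only, and peaks are not replicates.

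Lists on dm6 were joined to the Release 6 genome sequence and to its Ensembl annotation, release 115, which carries FlyBase release 6.54. Main arms were 2L, 2R, 3L, 3R, 4, X and Y, with 137547960 bases in all. The annotation gave 13968 protein-coding genes and 23694 positions of transcription start sites (TSSs) of all genes. The starts of 5889 annotated transposable elements were left out of the TSSs, a choice made once the annotation was seen, and counting them was tried as an alternative. Lists on dm3 were used for peak numbers, widths, signals, arm shares and 1 alternative of the replicate comparison, since a dm3 sequence or annotation was not used here. Coordinates are 1-based and were never converted between builds.

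The tests, the 22 gene lists, the 18 motifs and the rule for naming genes were fixed before the data were examined. To compare replicates, the 3170 peaks of highest signal in each replicate (N, the length of the optimal dm6 list) were taken. Summits within 100 bp of each other counted as shared. A 2-sided exact binomial test set the shared count against the share of main-arm bases within 100 bp of the other replicate's summits. The promoter share was the share of summits within 500 bp of a TSS, set against the share of bases there with an exact binomial test. Each summit also received 1 of 7 classes, in the order promoter, 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic. Classes and arms were tested with exact binomial tests and Benjamini-Hochberg adjustment, with a threshold of 0.05. The trend of promoter location with signal was tested by permutation with 100000 resamples. A gene was called bound when an optimal summit lay within 500 bp of 1 of its TSSs. Gene lists were compared with all other protein-coding genes by 2-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists. Of 1107 listed entries, 1102 were found among the protein-coding genes, older symbols included.

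For motifs, summit-centred windows of 200 bp were set against 3 control windows per peak. Control windows lay more than 1000 bp from any relaxed pooled summit and were matched on promoter class and on GC content in bins of 5 percentage points. Motifs and all 7-mers, with reverse complements merged, were compared by Fisher's exact tests with Benjamini-Hochberg adjustment within each family. Shares carry 95% exact (Clopper-Pearson) intervals and odds ratios carry 95% Wald intervals, with a continuity correction where a count was 0. For a count of 0 the upper limit corresponds to 3 counts. Values of the replicates come from each replicate's own N strongest peaks.

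Named genes followed a fixed rule. It took the 25 optimal peaks of highest signal that had a summit within 100 bp among the N strongest of both replicates. Each was named by the protein-coding gene with the nearest TSS or, with no TSS within 2000 bp, by the gene it lay in where it lay in 1. The rule also took hng1, hng2 and hng3, up to 4 bound members of each list with the strongest peaks, and the 10 7-mers with the smallest p and an odds ratio above 1. A gene named outside the rule is said to be so where it appears.

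Parts of the methods were tested on simulated data, with 3170 peaks for the promoter, class, arm and replicate tests. The gene-list test drew random genes rather than peaks. The 7-mer test set random windows against other random windows, without controls matched on GC content or promoter class. The simulations therefore do not give the number of 7-mers to be called by chance in the matched comparison. Random peaks gave a promoter share of 13.2% and 0 classes or arms past the threshold. A planted promoter share of 39.3% was recovered as 39.3%. With 1 of the 22 gene lists planted, 1 was called. With no planted 7-mer 0 of 8192 passed, and with 1 planted it ranked 1 of 8 called, of which 7 shared 5 bases with it. Planted replicate sharing of 40% was recovered as 40.4%, and unrelated lists shared 0.473%.

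Alternatives tried were other sharing distances and numbers of peaks, the stronger part of the optimal list (the 1585 peaks of highest signal), each replicate alone, other distances to a TSS, other TSS sets, other backgrounds, other motif windows and controls, and other k-mer lengths. Arm shares of dm3 peaks were not tested because dm3 arm lengths were not used here. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used, with the random seed 7.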

Results

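Binding of GFP-tagged hng2 was mapped by ChIP-seq, anti-GFP by the sample description, in Drosophila embryos aged 0 to 14 h, in 1 group of 2 biological replicates (numbers 2 and 3). The series gives no comparison between conditions, so the questions were where the tagged protein was found, at which genes and sequences, and how far the replicates matched. The optimal list on dm6 held 3170 peaks, all on the main arms. They were the 3170 peaks of highest signal among the 30000 relaxed pooled peaks. Their signal ran from 137 to 22810 with a median of 213. Their median width was 400 bp, and 86.0% had exactly that width. The depth of each library is unknown because the lists hold no counts. All positions below are on dm6 unless dm3 is named.

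The gene carried by the tagged transgene, hng2 (FBgn0037634, 3R, 8806322 to 8807581), had no optimal summit at its own promoter. The 1 optimal summit within the gene or 2000 bp to each side lay at 8808720, at rank 393 with a signal of 486. It was 2398 bp from the TSS of hng2 and 1091 bp from the nearest TSS, that of CG9837. The strongest summit near the gene ranked 360 in replicate 2, at 8808715, and 630 in replicate 3, at 8808591. A transgene can add DNA of its own locus, so a peak here does not separate binding from extra template. Of the related genes, hng3 (FBgn0035160, 3L) had an optimal summit at 738931, 418 bp from its TSS, at rank 317 with a signal of 549. For hng1 (FBgn0034599, 2R) there was 0 in the optimal list, and its strongest relaxed pooled summit ranked 11017.

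The highest of all peaks was in the gene for the Dpp receptor thickveins (tkv, FBgn0003716), at 2L, 5236428 to 5238352, with its summit 143 bp from a TSS and a signal of 22810. It ranked 1 in both replicates. An intergenic peak on 3R, 17231496 to 17232352, had a signal of 13082. The nearest TSS of a protein-coding gene, that of CG31262 (FBgn0051262), was 8832 bp away. A peak 1017 bp from a TSS of the potassium channel gene Shab (FBgn0262593), at 3L, 2893407 to 2894453, had a signal of 12546. Next came peaks in the 3' UTR of CG13310, at the promoter of the mannose phosphate isomerase gene Mpi and at the promoter of Spn (Spinophilin), with signals of 12324, 11248 and 10883.

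The rest of the 25 peaks also had a summit within 100 bp among the N strongest of both replicates. They included promoters of the insulin receptor gene InR, the GATA factor gene srp, the LIM protein gene Lmpt and the G-protein regulator gene loco. The summit at InR was 11 bp from a TSS and the summit at srp 52 bp. Peaks inside introns included those in the Notch coactivator gene mam, in the myoblast fusion gene rols and in the thrombospondin gene Tsp. An intergenic peak lay 2910 bp from the TSS of the pair-rule gene hairy (hry), and a coding-exon peak lay in Exn. Others were named by Rh5, regucalcin, CG13917, CG45088, CG13722, CG4622, Mipp1, Tep3 and CG2841. The limit of 100 bp left out the optimal peak ranked between those at Spn and Rh5. It had such a summit in replicate 3 but not in replicate 2, which does not show that it was absent there. Of the 25, 12 were at promoters, 6 in introns, 4 intergenic, 2 in 3' UTRs and 1 in a coding exon. Their signals ran from 3956 to 22810 and their ranks in replicate 3 from 1 to 29.

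The replicates shared far more of their strongest sites than their share of bases, the peak at tkv first among them. Of the 3170 strongest peaks of replicate 2, 1586 had a summit within 100 bp among those of replicate 3, against 0.463% of bases. That was 108-fold more than the base share (exact binomial log10 p = -2753), and the count was the same in the other direction. The base share treats all bases alike, although summits of both replicates were commoner at promoters. The test therefore does not show that the shared sites are particular to the tagged protein. Of the optimal peaks, 84.4% had a summit among the strongest of replicate 2 and 62.8% among those of replicate 3. Both held 1598 of them, 1079 were held by replicate 2 alone, 394 by replicate 3 alone and 99 by neither. In the full relaxed lists 97.3% of the optimal peaks were found in replicate 2 and 91.7% in replicate 3. Across the shared peaks, which are not independent replicates, Spearman's rho of the signals was 0.598 and Pearson's r of the log2 signals was 0.810. The optimal peaks are the strongest of the pooled libraries, so the weakest of them lie at the rank limit by construction and a lower share held by both is fixed there in advance.

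**Figure D1:**
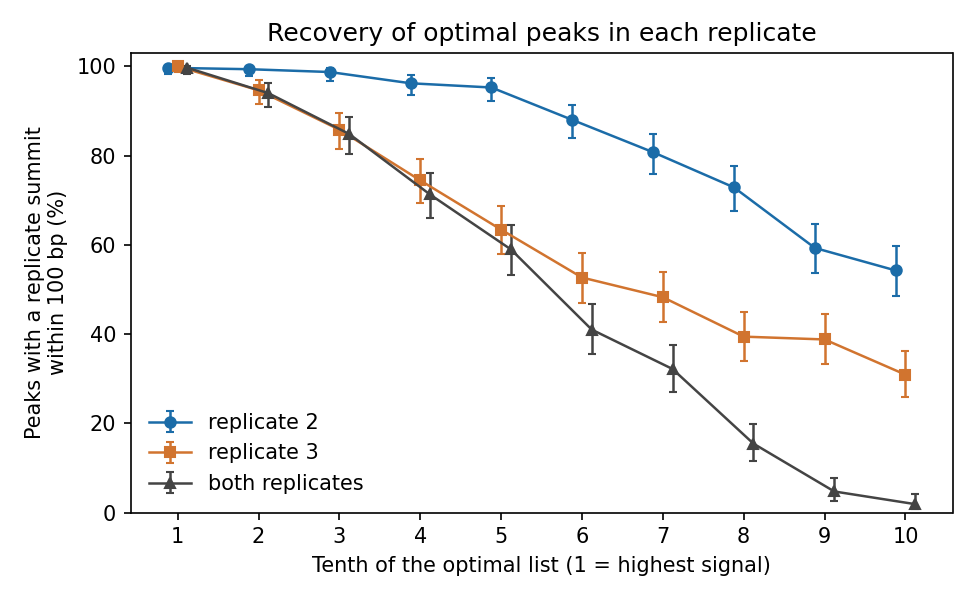
Share of optimal peaks (%) with a summit within 100 bp among the 3170 strongest peaks of replicate 2, of replicate 3 and of both, in 10 sets of 317 optimal peaks from the highest signal (1) to the lowest (10). Points are shares and bars are 95% exact intervals; the share held by both replicates falls along the list, as the rank limit requires for the weakest peaks, and replicate 2 holds 84.4% of all 3170 against 62.8% for replicate 3.

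Promoters held far more of the summits than their share of the genome, and coding exons far less. Of the optimal summits, 1317 (41.5%, 95% CI 39.8 to 43.3) lay within 500 bp of a TSS, against 13.3% of main-arm bases. This was a 3.13-fold excess (exact binomial log10 p = -337). The replicates' own lists gave 40.9% for replicate 2 and 47.1% for replicate 3, 44.0% ± 4.39 (SD, n = 2). Coding exons held 0.726% of summits against 13.4% of bases (Benjamini-Hochberg adjusted exact p = 1.76e-158). In 3' UTRs the share was 0.789% against 4.31% (adjusted exact p = 4.03e-32). Intergenic sequence held 14.8% of summits against 28.3% of bases (adjusted exact p = 1.64e-72). Exons of non-coding RNAs held 1.39% against 0.821% (adjusted exact p = 0.00149). Introns held 40.1% of summits against 39.1% of bases (adjusted exact p = 0.302), and 5' UTRs outside promoters 0.694% against 0.758% (adjusted exact p = 0.759); neither difference passed the threshold. The intron share fell below the base share in replicate 3's own list, by 0.092 on the log2 scale, and the 5' UTR share did so in replicate 2's, by 0.78; both passed the threshold there.

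Stronger optimal peaks were at promoters somewhat more often than weaker ones. The promoter share was 50.6% (95% CI 46.7 to 54.6) in the fifth of peaks with the highest signal and 38.2% (34.4 to 42.1) in the fifth with the lowest. Across peaks, Spearman's rho between signal and promoter location was 0.0780 (permutation p = 2e-05, with 100000 resamples). In the strongest peaks of replicate 3's own list, ranked by their signal there, rho was -0.0026 (permutation p = 0.883). In those of replicate 2 it was 0.121, so the trend was not seen in the peaks of replicate 3. These sets differ from the optimal list in their peaks as well as in their ranking.

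The small arm 4, which is largely heterochromatic, and the Y held few or no peaks. Arm 4 had 9 summits, 0.284% against 0.980% of bases (0.290-fold, Benjamini-Hochberg adjusted exact binomial p = 1.89e-05). No peak was listed on the Y in any of the dm6 lists, relaxed ones included, against 2.67% of bases. Whether reads can be placed on the Y was not tested, so this does not measure binding there. Arm 2L held 19.6% of summits against 17.1% of bases (1.15-fold, adjusted exact p = 0.000492). The shares of 2R, 3L, 3R and X did not differ from their bases past the threshold. Measured against TSS clusters in place of bases, the excess on 2L no longer passed (1.06-fold), 3L was 1.13-fold over and 2R was 0.840-fold. In the replicates' own lists 2R and 3L passed in replicate 2 alone and 3R in replicate 3 alone. The X passed in both with opposite signs, with a log2 ratio to its bases of 0.12 in replicate 2 and -0.23 in replicate 3.

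Genes for cytoplasmic ribosomal proteins stood out among the bound genes. In all, 1445 of 13968 protein-coding genes (10.3%) had an optimal summit within 500 bp of a TSS. The replicates' own lists gave 1478 and 1460 genes, 1469 ± 12.7 (SD, n = 2), with 836 genes in both. Of 92 ribosomal protein genes, 59 (64.1%, 95% CI 53.5 to 73.9) were bound against 9.99% of other genes. The odds ratio was 16.1 (95% CI 10.5 to 24.8, Benjamini-Hochberg adjusted Fisher's exact p = 1.90e-34 over 22 lists). Replicate 2 held 61 of them and replicate 3 held 56, 63.6% ± 3.84 (SD, n = 2). Among the strongest were RpS27 (FBgn0039300, 3R, summit 25247510, signal 759), RpLP0 (signal 586) and RpL7 (signal 511). Other genes of protein synthesis and turnover did not differ from the remaining genes past the threshold. Bound were 9 of 73 mitochondrial ribosomal proteins (adjusted exact p = 0.650), 8 of 52 translation factors (adjusted exact p = 0.367) and 3 of 48 proteasome subunits (adjusted exact p = 0.584). Their strongest members were mRpS10 and mRpS23, eIF4EHP and eEF1gamma, and Rpn2, Rpn9 and Rpn11. Of 80 nuclear-encoded respiratory chain genes 4 were bound (adjusted exact p = 0.279), ND-ASHI, ND-MWFE, ND-42 and ND-51.

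Heat shock genes and genes of dorsoventral and mesoderm patterning passed the threshold above other genes, each with few members. Both calls were lost with a shorter distance to a TSS, with intervals over a TSS, with the stronger part of the optimal list and with a background limited to genes near a relaxed summit. The log2 odds ratio of the dorsoventral list was 1.64, 1.64, 1.36 and 1.84 in these settings against 1.73, and that of heat shock genes 1.25, 0.44, 1.68 and 1.97 against 1.84. Of 24 heat shock and chaperone genes 7 were bound, an odds ratio of 3.58 (95% CI 1.48 to 8.65, adjusted Fisher's exact p = 0.0326). Hsp27 had a signal of 754, Hsp83 of 700, Hsc70-5 of 216 and Hsp22 of 215. The replicates' own lists held 6 and 5 of the 24, and the list passed the threshold in neither. Of 29 dorsoventral and mesoderm genes 8 were bound, an odds ratio of 3.31 (95% CI 1.47 to 7.5, adjusted Fisher's exact p = 0.0326). They included the GATA cofactor gene ush with a signal of 3041, the axon guidance gene NetB with 1749, the heart gene tin with 347 and the FGF pathway gene stumps with 339. Replicate 2 held 6 of the 29 and replicate 3 held 9, and the list did not pass in replicate 2 alone.

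Genes of sensory reception, histones and cuticle were bound less often than others. None of 179 chemosensory receptor genes was bound in the optimal list, which allows a share of up to 1.68% (adjusted Fisher's exact p = 7.00e-08), and each replicate's own list held 1. For canonical histone genes it was 0 of 111, up to 2.70% (adjusted Fisher's exact p = 8.08e-05), but these are near-identical repeated copies to which reads are hard to assign. Of 95 cuticle genes 1 was bound, Cpr76Bc (odds ratio 0.0916, adjusted Fisher's exact p = 0.00320). The cuticle call was lost with the stronger part of the optimal list, with intervals over a TSS and with the limited background, where the log2 odds ratio was -2.57, -2.67 and -2.71 against -3.45.

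The remaining lists did not pass the threshold. Insulator and architectural proteins came closest, with 6 of 22 bound (adjusted Fisher's exact p = 0.0665), among them Chro, Cp190, Dref and M1BP. Bound Polycomb and Trithorax group genes were 7 of 34 (adjusted exact p = 0.196), with ph-p, brm, E(z) and Trl the strongest. Hox and Polycomb-target regulators were 8 of 38 (adjusted exact p = 0.147), with srp, lbl, Dll and lbe. Wing hinge and appendage genes, for which hng2 is named, were 6 of 29 (adjusted exact p = 0.252), with Dll, hth, noc and tsh. All 4 of these lists passed the threshold in replicate 3's own list, and of the 4 the Polycomb and Trithorax group alone passed in replicate 2's. The insulator list also passed with a shorter distance to a TSS, with intervals over a TSS and with the stronger part of the optimal list. The Hox list passed with the first 2 of these settings and with each summit given to its nearest TSS, and the wing list with intervals over a TSS. DNA replication and cell cycle genes were 7 of 40 (adjusted exact p = 0.338), including RnrS, Dp, CycE and Cdc7. Segmentation genes were 3 of 34 (adjusted exact p = 1), namely hry, ptc and oc, and early zygotic genes 0 of 20 (adjusted exact p = 0.367). MADF and BESS domain genes were 2 of 9 (adjusted exact p = 0.367), hng3 and jigr1. Of the tissue markers, bound genes were 1 of 27 neuronal (elav), 3 of 24 muscle (Tm1, sls and Act87E), 2 of 21 gut and fat body (srp and fkh) and 4 of 21 hemocyte and trachea genes (srp, ush, trh and bnl), with adjusted exact p from 0.367 to 1. Some of the peaks at named members were not among the 3170 strongest of both replicates. In replicate 3 the peaks at Rpn11, ND-MWFE, ND-51, CycE, Hsc70-5, Hsp22, sls and Act87E ranked below the 3170 strongest and those at ND-42, jigr1, M1BP, Trl and trh had no summit within 100 bp, although M1BP, Trl and trh were bound there at another summit. In replicate 2 the peaks at ptc, oc, lbe, noc and tsh ranked below the 3170 strongest and that at CycE had no summit within 100 bp, so the CycE peak met the limit in neither replicate.

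**Figure D2:**
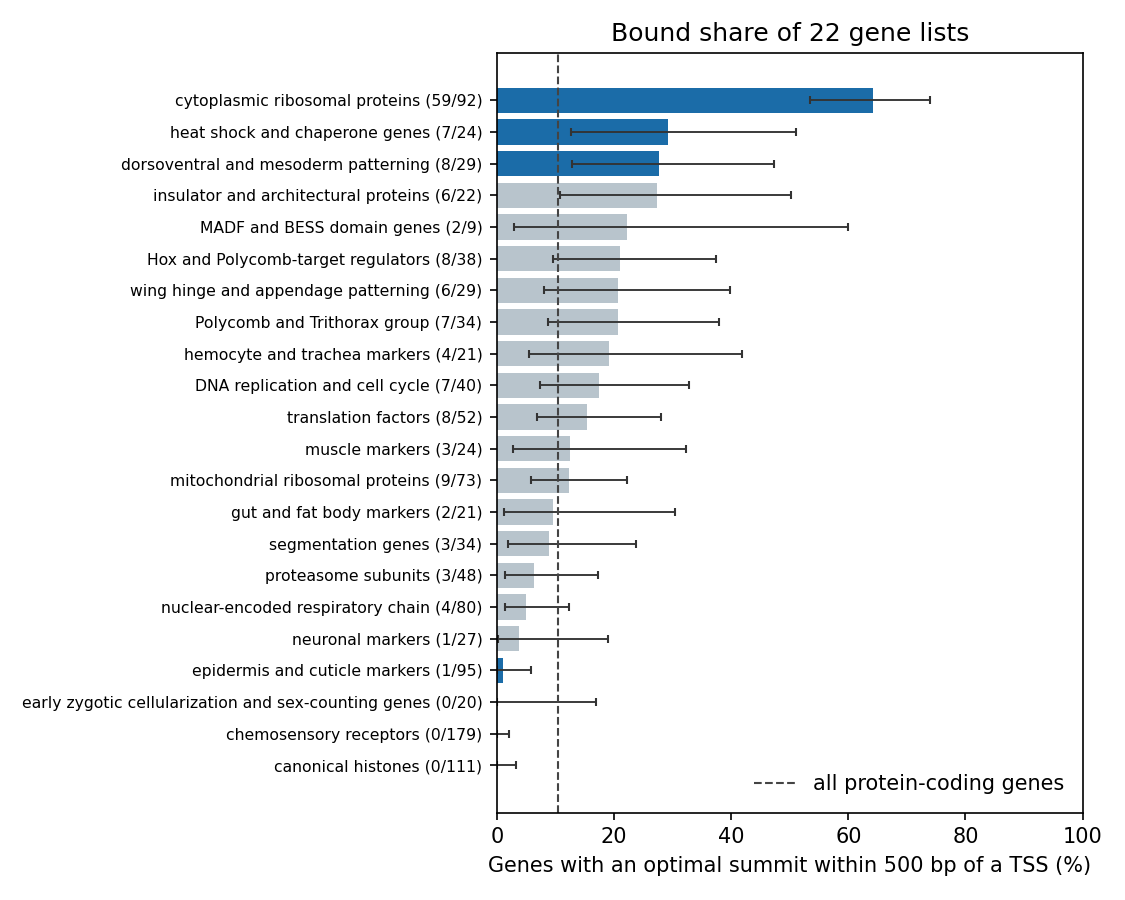
Share of the genes of each of 22 lists with an optimal summit within 500 bp of a TSS (%), with 95% exact intervals and the counts bound and found beside each name. The dashed line is the 10.3% of all protein-coding genes; cytoplasmic ribosomal proteins lie at 64.1%.

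Of 18 motifs, 6 were found under the peaks more often than in matched windows, those of CTCF and GAGA factor with the smallest p. The CTCF consensus was in 1.45% of peak windows and 0.105% of control windows, an odds ratio of 14.0 (95% CI 7.05 to 27.8, Benjamini-Hochberg adjusted Fisher's exact p = 6.34e-18 over 18 motifs). Its log2 odds ratio was 3.81, with 4.19 in replicate 2's own list and 1.96 in replicate 3's, 1.90 in windows of 400 bp and 2.02 against flanking windows, and it passed in each. GAGA factor repeats were in 4.61% against 1.64% (odds ratio 2.89, adjusted exact p = 8.05e-18), a log2 odds ratio of 1.53, with 1.23 in replicate 2's own list and 2.23 in replicate 3's. The core promoter element Ohler 7 had an odds ratio of 1.95 (adjusted exact p = 2.04e-05). The E-box CAGCTG, the Adf1 site, bound by another MADF and BESS domain protein, and CA repeats had odds ratios of 1.37, 1.52 and 1.44 (adjusted exact p = 0.000449, 0.00331 and 0.00294). None of these 3 passed with the stronger part of the optimal list, at log2 odds ratios of 0.33, 0.65 and 0.18, or in windows of 100 bp, at 0.38, -0.013 and 0.47. The other 12 motifs, among them DRE, BEAF-32, Motif 1, Zelda, su(Hw), Pita and ZIPIC, did not pass. Against windows 1000 bp to either side of the same summits, the log2 odds ratio of GAGA repeats was 0.21 and no longer passed. CA repeats did not pass in replicate 2's own list either, with 0.23 there and 1.19 in replicate 3's. With the flanking windows the values of CAGCTG, Adf1 and CA repeats turned negative, at -0.19, -0.49 and -0.26, and that of Adf1 passed the threshold in this direction. DRE, su(Hw), BEAF-32 and the TATA box passed against the flanking windows, at 1.73, 3.17, 0.54 and 0.61. In windows of 400 bp DRE, Motif 1 and Ohler 6 were over-represented past the threshold, at 0.69, 1.56 and 0.91, and the initiator was under-represented, at -0.15, as it was with the stronger part of the list, at -0.26. Motif 1 also passed in replicate 2's own list, at 1.17.

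A pair of short cores ran through the 7-mers most over-represented under the peaks. Of 8192 7-mers, 493 were over-represented and 438 under-represented past the threshold; neighbouring 7-mers overlap and are not independent. The 10 with the smallest p were ACAGTGG, CAGTGCA, CAGTGTA, AAACGCG, CACAGTG, CACTGAG, CGCGCGC, AACGCGC, CACTGTA and AGTGCAC. ACAGTGG was in 7.57% of peak windows and 1.87% of control windows (odds ratio 4.29, 95% CI 3.52 to 5.24, Benjamini-Hochberg adjusted Fisher's exact p = 9.76e-43). CGCGCGC was in 2.56% and 0.294% (odds ratio 8.88, 95% CI 5.77 to 13.7, adjusted Fisher's exact p = 3.19e-24). Grouped by core after the result was seen, 7 hold CAGTG on either strand in whole or in part and 3 hold CGCG. A 7-mer of the CGCG group was in 35.0% of the 317 peaks of highest signal and in 2.84% to 7.26% of each later set of 317, against 2.17% of control windows. A 7-mer of the CAGTG group was in 29.0% of all optimal peaks against 10.9% of control windows, and the share ranged from 22.7% to 38.5% over the same 10 sets.

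**Figure D3:**
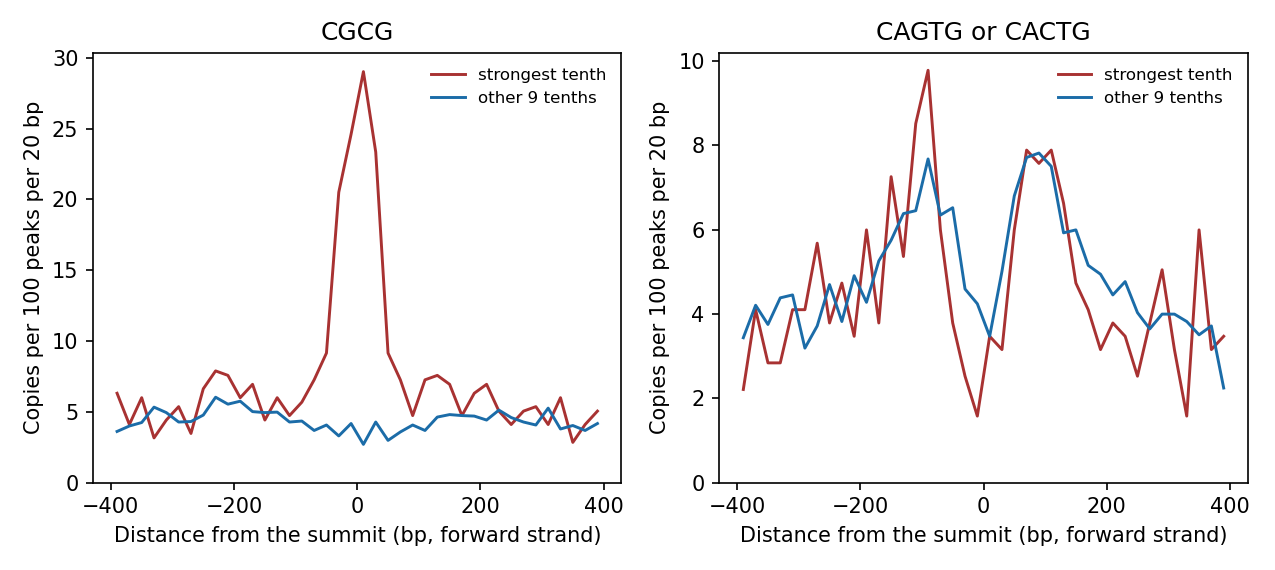
Copies of the CAGTG and CGCG cores per 100 peaks in each 20 bp step across 400 bp to each side of the summit, for the 317 optimal peaks of highest signal and for the other 2853. In the strongest 317 CGCG averages 24.1 copies per step within 40 bp of the summit; CAGTG copies are densest beside the summit in both sets of peaks.

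The strongest peaks matched between the genome builds by arm and by signal. The optimal list on dm3 held 2400 peaks against 3170 on dm6. The 25 peaks of highest signal lay on the same arm at the same rank in both builds, with signals that differed by at most 0.0914%. Arm shares of the optimal lists differed by at most 0.319 percentage points, on the X, and those of the stronger part of each list by at most 0.672.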

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

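The grouping of the 7-mers by core, the values for weaker pooled peaks, and the tests of the CAGTG group with their distances were chosen only after the results were seen. The 4 tests of the CGCG group were set out beforehand. There is 1 group of samples, so no explanation that needs a comparison of conditions was tested for either group of 7-mers.

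Both groups of 7-mers also appeared in pooled peaks that the comparisons of the report do not use. In the 3170 relaxed pooled peaks ranked next below the optimal list, the CGCG group was in 4.89% of windows against 2.57% of matched windows, an odds ratio of 1.95 (95% CI 1.59 to 2.40). The CAGTG group was in 22.6% against 11.7%, an odds ratio of 2.21 (95% CI 1.99 to 2.45). In the optimal list the odds ratios were 3.78 and 3.35. Further sets of 3170 were taken down the pooled list, with the optimal list as set 1. The CAGTG odds ratio was still 1.30 (95% CI 1.16 to 1.46) in set 9, and its interval stayed above 1 in every set. The CGCG odds ratio was 1.26 (95% CI 0.997 to 1.58) in set 7 and 1.13 (95% CI 0.890 to 1.44) in set 9. In the other sets its interval stayed above 1. The CAGTG excess was thus also seen in windows of weaker peaks. The 7-mers were chosen in the optimal list and the values for these weaker peaks come from other summits of the same libraries. No distance from the optimal summits was required, so some of these windows may share sequence with windows of optimal peaks.

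The CGCG 7-mers marked the strongest peaks, where 111 of the first 317 carried 1. Windows matched to these peaks on GC content and promoter class carried them less often, with an odds ratio of 26.4 (95% CI 15.9 to 44.0). The 7-mers were chosen for an excess over windows matched in the same way, in peaks that include these. A high ratio was thus built in, and it does not decide on base composition. Annotated transposable elements as the whole cause are argued against by an overlap of 0 of the 111 peaks, which allows up to 2.70%. Of all 3170 optimal peaks, only 9 overlapped such an element. The excess of CGCG 7-mers was present in both replicates. The odds ratio of the strongest 317 against the rest was 11.3 in replicate 2 and 7.93 (95% CI 6.06 to 10.4) in replicate 3. Both replicates' lists hold most of the optimal peaks in which the 7-mers were chosen, so these ratios are not independent of that choice. Of the copies within 500 bp of these summits, 54.8% (95% CI 48.5 to 60.9) lay within 50 bp, against 10% for an even spread and 10.7% in the other 2853 peaks, but the interval reaches below the 50% set for a central sequence, and choosing the 7-mers in windows around these summits raises that share by itself. A sequence bound directly at the strongest peaks may account for the pattern, as may sites that give a strong signal with any antibody or tag, which could not be tested without control libraries.

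The CAGTG 7-mers lay beside the summits of the optimal peaks rather than on them. Copies of the core numbered 7.11 per 100 peaks and 20 bp at 40 to 120 bp from the summit and 4.16 within 40 bp, both inside or near the windows in which the 7-mers were chosen, and a central site is argued against by the 11.4% (95% CI 10.4 to 12.5) of 7-mer copies within 50 bp. The group was over-represented in both replicates, with odds ratios against matched windows of 3.63 in replicate 2 and 2.19 (95% CI 1.97 to 2.43) in replicate 3. The 7-mers were chosen in the optimal list, of which these 2 sets of peaks hold 84.4% and 62.8%. Ratios above 1 in both were therefore likely beforehand. The position of the core beside the summits was weaker in replicate 3, with 5.76 copies there against 4.50 within 40 bp. In replicate 2 the values were 7.45 against 3.87. A sequence preference at fragment ends stays open: 54.9% (95% CI 52.5 to 57.2) of copies beside the summits had CACTG on the left or CAGTG on the right (exact binomial p = 4.12e-05), while the strongest 317 had 44.0% (exact binomial p = 0.119). A lean this small may reflect such a preference in part of the peaks, and the reads needed to test it were not analysed here.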

How the results depend on the processing

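The alternatives for the 7-mers other than length and flanking controls, those without arm Y and the one that counts starts of transposable elements as TSSs were chosen only after the data were seen. A sign change with neither setting past the threshold was counted as no change, a rule also set after a first run; it covers 45 comparisons of single classes, arms, lists or motifs. Of the alternatives for the main values of the comparisons, 49 kept the direction and side of the threshold or left a count within 1.5-fold, 10 changed a count further, and 1 took the value to near 0 with the opposite sign. Within that allowance the gene lists past the threshold still ran from 4 to 9, against 6.

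Replicate sharing stayed above its base share in all settings. It ran from 34.8% with all relaxed peaks (7.93-fold over the base share) to 57.4% with the stronger peaks of each replicate (248-fold). The dm3 setting took the largest peak end on each arm as its length. The promoter share kept its direction in all settings, from 25.3% to 51.9%. The number of feature classes past the threshold was 5, with 6 in either replicate alone, where the log2 ratio of introns ran from -0.092 without replicate 2 to 0.036 without replicate 3, against 0.036.

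The signal trend was lost in replicate 3's own strongest peaks, with rho of -0.0026 (permutation p = 0.883) against 0.0780 in the optimal list. Both the peaks and their ranking differ there, and the cause was not tested. Arms past the threshold went from 3 to 5 to 6 with a replicate left out; the log2 ratio of the X was then -0.23 without replicate 2 and 0.12 without replicate 3. Bound genes fell to 823 with the stronger part of the list, which has fewer peaks, and to 879 when the peak interval had to cover a TSS. Gene lists past the threshold went from 6 to 2 when the background was limited to genes near a relaxed summit, which leaves fewer genes and none of the canonical histones, so that list was not tested there. Ribosomal proteins passed in all settings. The heat shock list lost its call in each replicate alone and the dorsoventral list in replicate 2 alone, and both lost it with a shorter distance to a TSS, with intervals over a TSS, with the stronger part of the list and with the limited background. The cuticle list lost it in the last 3 of these, with log2 odds ratios of -2.67, -2.57 and -2.71 against -3.45. With the limited background the log2 odds ratios were as large as before, 1.84 against 1.73 for the dorsoventral list and 1.97 against 1.84 for heat shock, with fewer genes to test; heat shock fell to 1.25 with the shorter distance and 0.44 with intervals, and the dorsoventral list stayed at 1.64 in each. Calls were also gained: the insulator, Hox, wing and Polycomb lists in settings the report names.

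Motifs past the threshold went from 6 to 3 in windows of 100 bp and 10 in windows of 400 bp; with the stronger part of the list they were 4, with CAGCTG, Adf1 and CA repeats lost and the initiator gained at -0.26. In 100 bp windows Adf1 had a log2 odds ratio of -0.013. With flanking windows as controls, CAGCTG was at -0.19, the TATA box at 0.61, Adf1 at -0.49 and CA repeats at -0.26; the cause was not tested. Of these, Adf1 and the TATA box passed the threshold, and DRE (1.73), su(Hw) (3.17) and BEAF-32 (0.54) gained a call. Flanking windows are not matched on GC content or promoter class. Over-represented 7-mers were 493, against 772 with flanking windows, 242 with the stronger part of the list and 277 with 6-mers, of which fewer exist. The 10 named 7-mers kept their direction and side of the threshold in the settings run for them. The depth of the libraries is unknown, so what it limits could not be assessed. The arm shares of dm3 peaks were not run, since dm3 arm lengths were not used here.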

Other observations

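The test of chance for the patterning genes, the values for ribosomal protein promoters and those for motif pairs were chosen only after the results were seen. The ribosomal protein values were first computed to weigh explanations of that result (housekeeping genes in general, a lack of the 7-mers, 1 library) and are given here as values only. The test of weaker summits in replicate 2 was set out beforehand.

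Ribosomal protein promoters were bound close to the TSS. The median distance from the summit to the TSS was 28 bp for the 59 bound genes and 166 bp for other bound genes. The median signal of the 59 was 263, against 235 for other bound genes. Of all 92 ribosomal protein genes, 51 were bound in both replicates' own lists. Genes for mitochondrial ribosomal proteins, proteasome subunits and the respiratory chain are also widely expressed, and these 3 lists pooled had 16 of 201 genes bound, 7.96% against 10.0% of remaining genes (odds ratio 0.777, 95% CI 0.465 to 1.30, Fisher's exact p = 0.406). With translation factors added, 24 of 253 genes (9.49%) were bound against 10.0% (odds ratio 0.943, 95% CI 0.617 to 1.44, Fisher's exact p = 0.916). Of the ribosomal protein peaks 14 of 59 held a 7-mer of either core, against 394 of 1258 other promoter peaks (odds ratio 0.682, 95% CI 0.370 to 1.26). Among the pooled peaks ranked next below the optimal list, 16 of the 92 ribosomal protein genes had a summit within 500 bp of a TSS (odds ratio 2.04, Benjamini-Hochberg adjusted Fisher's exact p = 0.0969). Chemosensory receptor genes, with 1 of 179, were below other genes there too. Canonical histones were at 0 of 111, but reads are hard to assign to these near-identical copies, so this count does not measure binding.

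The promoter share fell along the pooled list, from 41.5% in the optimal peaks to 37.5% in the next 3170 and 19.1% in the ninth such set. GAGA repeats and the CAGTG 7-mers tended to lie in different peaks: 19.2% of peaks with GAGA repeats held a CAGTG 7-mer, against 29.4% of other peaks (odds ratio 0.569, Benjamini-Hochberg adjusted Fisher's exact p = 0.0268 over 4 pairs). The test does not account for location: GAGA repeats were in 6.15% of promoter peaks and 3.51% of others, and CAGTG 7-mers in 23.2% and 33.1%. Of the optimal peaks, 9 of 3170 overlapped an annotated transposable element.

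Regulators of body plan and appendages were bound in replicate 3 more than in replicate 2. Of the 63 genes in the Hox and Polycomb-target list and the wing hinge and appendage list, 19 were bound in replicate 3 and 4 in replicate 2, with 15 in replicate 3 alone and 0 in replicate 2 alone. The 15 were Abd-B, C15, Dr, Egfr, Lim1, bab2, dve, eyg, lbe, noc, pnr, sd, tio, tsh and zfh2; they were named after their values were seen. Whether chance gave this could not be decided, since both lists were picked for differing and each side is 1 library. Among genes bound in 1 replicate alone, Fisher's exact tests gave a Benjamini-Hochberg adjusted p of 0.0183 in both lists, over all 22. These tests took the place of a first test on both lists pooled. The 2 lists share genes, Dr, tio and tsh of the 15 among them, so the 2 tests are not independent. A limit of rank in replicate 2 stays open too: 66.7% of the 15 (10 genes, 95% CI 38.4 to 88.2) had a weaker summit there, against 76.0% of other genes bound in replicate 3 alone, so the difference may be of degree, and embryo age within the collection or another difference between the libraries could not be tested.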
